A study of Homo sapiens and Mus musculus with 19 samples.

How the data were processed

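Total RNA was isolated with an RNeasy kit, amplified with a whole-transcript expression kit and labelled with biotin, per the labels' protocols, and hybridised to whole-transcript gene arrays, 17 for human cells and 2 for mouse cells. The deposited values are log2 expression values, 1 per row of the array, made with RMA (background correction, quantile normalization and summary of probes) in Affymetrix Expression Console, per the submitters' processing notes. Versions of both are not given in the sources used here, nor is whether the arrays of a species were normalized in a single run. There were 33297 human and 35556 mouse rows, and no column fell outside the samples used here. RMA forces the arrays to alike distributions, so a change shared by most genes would not appear, and it pulls differences of dim rows toward 0. Array medians lay between 6.918 and 7.044 (human) and at 6.598 and 6.621 (mouse), and the 30th percentiles of the human arrays between 5.565 and 5.687. Arrays have no read depth, so the number of arrays and the signal of a row limit the precision.

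Groups were taken from the sample titles. The 10 hepatocyte arrays form 5 donor pairs of Ad-GFP and Ad-PGC-1alpha, numbered by donor in the labels. The 7 HepG2 arrays are single arrays for each combination of siRNA (none, control or HSF1) and virus, and the 2 C2C12 arrays are 1 per virus. Rows were named from the platform's annotation table. Of the human rows 19460 had 1 gene symbol, 1754 had several and 12083 were not listed with a gene. Of the mouse rows 21789 had 1 symbol, 1621 several and 12146 were not listed. For 19429 human rows with 1 symbol the gene ID was matched to RefSeq, and 0 symbols needed an update. Only rows with 1 symbol were used for named genes, and 42 sex-linked human rows were left out to keep donors private. Where a gene had several rows (767 human and 999 mouse genes) the row with the highest mean over the arrays of that species was kept, leaving 18377 human and 19938 mouse genes. Of 344 genes named in the rule, 18 had several rows, and in hepatocytes 1 of these, EPCAM, had rows of both signs (-0.13 and 0.18). The rows of TGIF1 ranged from -2.52 to -0.58, those of CACYBP from -1.37 to -0.53 and those of GABPA from 0.73 to 1.47. Some members of the gene lists were not analysed here.

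Genes above the 30th percentile of the array in at least 5 hepatocyte arrays, or at least 3 HepG2 arrays, were tested, which left 15388 genes in hepatocytes, 15204 in HepG2 and 16148 in the comparison of both (at least 3 of 16 arrays). Viruses were compared in hepatocytes with limma (lmFit and eBayes) on the log2 values, with the virus as the only term and 8 residual degrees of freedom. In HepG2 the virus and the siRNA state (none, control, HSF1) were terms of a fit over 6 arrays with 2 residual degrees of freedom, which also gave HSF1 siRNA minus control siRNA. Because the residual of that fit holds any difference of the virus effect between siRNA states, such differences widen its errors. The difference between the cells was tested with limma on the log2 ratios of 5 donor pairs against 3 HepG2 pairs. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. SE values are the square root of the moderated variance times the design factor, and SD values are over arrays of a group.

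The donor numbers in the labels pair the hepatocyte arrays. After subtraction of each virus mean, arrays of the same donor correlated between 0.677 and 0.707 and those of different donors between -0.603 and 0.686, and 5 of 5 Ad-GFP arrays were closest to the other array of their donor. The fit with the donor as a replicate block (4 residual degrees of freedom) is given beside a list or named gene whose call it changes, and beside counts of genes that it moves by over 1.5 times or where it adds the first rise or fall. No arrays held identical values.

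Gene lists were fixed before the data were examined, as were the tests, the filter, the rule for named genes and most of the other settings tried. The lists cover heat shock chaperones, the chaperonin and prefoldin, mitochondrial chaperones and proteases, the endoplasmic reticulum stress response, the proteasome, complex I, complexes II to IV, ATP synthase, the citric acid cycle, fatty acid oxidation, targets of PPAR alpha and the estrogen-related receptors (ERR), mitochondrial biogenesis, glucose handling, glycolysis, cholesterol, fatty acid synthesis, bile acids, xenobiotic metabolism, the urea cycle, antioxidant defence, interferon, inflammation, secreted hepatocyte proteins, cell cycle, p53 targets, angiogenic factors, muscle contractile genes and markers of macrophages, endothelium, stellate cells, cholangiocytes, lymphocytes, hepatocytes and myoblasts. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, 32 in the human comparisons, and again with an estimated correlation. With an estimated correlation camera takes the residual degrees of freedom of the fit, 8 in hepatocytes and 2 in HepG2. The preset form takes a number set by the count of genes instead. The estimated form therefore gives large p-values in HepG2 even for a wide shift. Counts adjusted over the list alone used Benjamini-Hochberg within each list. An exact two-sided permutation test on list means in hepatocytes, over 252 splits with a smallest possible p of 0.00794 and no use of the donor pairs, was added after seeing the data. Arrays of the same donor resemble each other, so they are not freely interchangeable and its p does not hold exactly. Only 16 divisions part every pair, too few for a share under 0.05.

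Comparisons of 1 array with 1 array (PGC-1beta, C2C12 and the separate HepG2 pairs) have no test. A list's median there is given as a percentile of 10000 random lists of the same size matched on mean level in 20 bins. Genes for the dependence on HSF1 siRNA were chosen by a difference of at least 1 log2 unit in the pair without siRNA, whose arrays take no part in the compared values. Chance correlation through the shared Ad-GFP array was simulated 100 times.

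The rule for named genes took PPARGC1A, PPARGC1B and HSF1 and, by size, the 10 largest rises and 10 largest falls in hepatocytes among genes past the threshold with the same sign in 5 of 5 pairs, and 5 of each that passed only with the replicate block. It took the 5 largest each way in HepG2 (same sign in 3 pairs), after HSF1 siRNA (same sign under both viruses, by size, since none passed), for the array labelled Ad-PGC-1beta against either other virus, and for hepatocytes against HepG2, and the 10 largest each way in C2C12. For single arrays the higher value had to reach the 50th percentile of its array. Up to 4 members of each list with the largest change were eligible. Small RNA genes, uncharacterised loci and HLA genes were left out of these rankings. Genes called in the 4-array fit of HSF1 siRNA, those shared by all cells, and ATF4 were named outside this rule, after their values were seen.

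The median log2 difference of all genes was 0.0296 in hepatocytes, 0.0343 in HepG2 and -0.0157 in C2C12, so no scaling moved it by over 0.1. Alternatives were the replicate block (fixed and random), each donor or pair left out, no filter and a filter at the 50th percentile, quantile normalization, median centring, a mean-variance trend, every row of a gene, a size threshold of 1 log2 unit (0.58 for the HSF1 comparison), an estimated correlation, fry in place of camera (planned in hepatocytes, added after seeing the data elsewhere), the fit without siRNA state and the fit of 4 siRNA arrays. Fits were tested on simulated data with 200 changed genes. In hepatocytes (15388 genes) 0% of changes of 0.5 log2 units, 46.5% of changes of 1 and 87% of changes of 2 were recovered, and 0%, 91.5% and 99% with the replicate block. Unchanged genes made up 0% of the calls at each size without the block, and 0%, 2.66% and 6.6% with it. For the virus effect in HepG2 (15204 genes) the shares were 0%, 98% and 100%, for HSF1 siRNA 0%, 94% and 100%, and for hepatocytes against HepG2 (16148 genes) 0%, 60.5% and 98.5%. Unchanged genes made up 0%, 7.11% and 5.66% of the calls for the virus effect in HepG2, 100% (3 of 3 calls), 6% and 10.3% for HSF1 siRNA, and 0%, 8.33% and 2.96% for hepatocytes against HepG2. A shift of 0.5 in the heat shock or the citric acid cycle list was called by camera, with 0 other lists. Noise was drawn independently for each gene there, so this does not test how often camera calls unchanged lists of correlated genes. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.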

Results

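Gene expression was measured on 17 human and 2 mouse whole-transcript arrays, read as RMA values on the log2 scale. Primary human hepatocytes of 5 donors had been infected with an adenovirus for green fluorescent protein (Ad-GFP) or with one labelled as carrying PGC-1alpha (Ad-PGC-1alpha), with 5 arrays for each virus. HepG2 cells, a human liver cancer line, gave 1 array for each of Ad-GFP, Ad-PGC-1alpha and Ad-PGC-1beta without siRNA, and 1 array for Ad-GFP and Ad-PGC-1alpha after a control siRNA and after an siRNA against HSF1. C2C12 cells, a mouse muscle line grown here as myotubes, gave 1 array for Ad-GFP and 1 for Ad-PGC-1alpha. Cells were collected 24 h after infection, siRNA had been given 48 h before infection, and C2C12 cells had been differentiated for 7 days. Array medians lay between 6.92 and 7.04 on the human arrays and were 6.60 and 6.62 on the mouse arrays, and the number of arrays limits the precision of every value. The title of the series sets PGC-1alpha, a transcriptional coactivator of mitochondrial and fasting genes, against the gene programs of HSF1, the main transcription factor of the heat shock response.

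The row for PPARGC1A, the gene that encodes PGC-1alpha, did not pass as higher in any human comparison of the arrays labelled Ad-PGC-1alpha. In hepatocytes it read 9.87 ± 0.23 (SD, n = 5) after Ad-GFP and 9.57 ± 0.11 (SD, n = 5) on the arrays labelled Ad-PGC-1alpha, a difference of -0.30 that did not pass the test (SE 0.13, adjusted p = 0.18 by limma). In HepG2, PPARGC1A read 9.09 after Ad-GFP and 8.98 on the array labelled Ad-PGC-1alpha, 9.43 and 9.295 with control siRNA, 9.78 and 9.79 with HSF1 siRNA (differences of -0.105, -0.131 and 0.012), and 9.69 on the array labelled Ad-PGC-1beta. The mouse row for Ppargc1a went the other way in C2C12, from 8.40 to 13.2, a value 28.2-fold higher, although a dimmer row of the same gene read 6.23 and 5.61. Because the human row does not bear out the label, these are called the arrays labelled Ad-PGC-1alpha throughout, and each direction given for them rests on that label. PPARGC1B, which encodes PGC-1beta, read 7.33 ± 0.21 and 7.00 ± 0.15 in hepatocytes (SD, n = 5 each), a difference of -0.33 that passed only with the donor as a block (adjusted p = 0.146 without and 0.0281 with it, limma). In HepG2 the PPARGC1B row read 7.51 after Ad-GFP and 7.165 on the array labelled Ad-PGC-1beta, so that label was not borne out by its row either. HSF1 read 9.76 ± 0.21 and 10.1 ± 0.22 in hepatocytes (SD, n = 5 each), was higher in 5 of 5 donors by 0.37 on average, and passed only with the donor block (adjusted p = 0.135 without and 0.0167 with it, limma). The HSF1 row read 9.94 with control siRNA and 8.82 with HSF1 siRNA under Ad-GFP, and 10.1 and 8.90 on the arrays labelled Ad-PGC-1alpha.

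The comparison of hepatocytes asked which genes differ between the viruses in normal human liver cells. CYP17A1, a steroid hydroxylase, had the largest rise, from 6.42 ± 0.58 to 10.3 ± 0.78 (SD, n = 5 each), which is 3.87 on the log2 scale (SE 0.39, adjusted p = 0.00118). PCK1 and G6PC1, enzymes of glucose production, rose by 3.49 (SE 0.60) and 2.94 (SE 0.47), and CYP11A1, which starts steroid hormone synthesis from cholesterol, rose by 2.73 (SE 0.29). The other large rises were those of LIFR, a cytokine receptor, at 3.32, SLC1A2, a glutamate transporter, at 2.75, C11orf86 at 2.74, JAKMIP2 at 2.72, TMEM116 at 2.71 and OXT, the oxytocin gene, at 2.68. HSPA6, a stress-induced chaperone, had the largest fall, from 12.4 ± 0.87 to 8.70 ± 1.17 (SD, n = 5 each), which is -3.72 (SE 0.57, adjusted p = 0.00386).

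MMP1, a collagenase, changed by -2.93, TRIB1, a pseudokinase, by -2.65, SNAI2, a repressor of epithelial genes, by -2.65 and TGIF1 by -2.50 in the hepatocytes. RASGEF1B changed by -2.41, GEM by -2.35, ARID5B by -2.28, MYC, a regulator of cell growth, by -2.25 and FRMD6 by -2.16. These 20 genes were chosen among those that passed with the same sign in 5 of 5 donors, so neither trait is a separate result. Their adjusted p lay between 0.000946 and 0.0239 in limma. Of 15388 genes tested, 1771 passed, 839 higher and 932 lower (953 and 829 after median centring), and 1757 of the 1771 had the same sign in all 5 donors. At least 1 log2 unit separated the viruses for 649 of them. With the donor as a block 4262 genes passed, 2048 higher and 2214 lower, and 1769 of the 1771 were among them. Genes that passed only with the block included PVALB at 3.01 (adjusted p = 0.106 without and 0.0445 with it), TMPRSS11E at 2.63, ECM1 at 2.38, CKMT2 at 2.33 and TRIM31 at 2.28, and, lower, ACTBL2 at -2.02, ITGA2 at -1.85, VIM at -1.74, NOD2 at -1.71 and ABCC2, a bile pigment exporter, at -1.66. MMP1 lost its call in 3 and GEM in 4 of the 5 fits without a donor pair, with adjusted p up to 0.0909 and 0.104. Leaving out replicate 3 left 1619 genes, and leaving out any of the other 4 replicates left between 753 and 983. With both arrays of a donor averaged, 3 donors lay apart from the other 2 on a component holding 71% of the variance among the 5 donor means. Within these sets the blocked fit called 3313 and 5821 genes. The set of 2 donors leaves few residual degrees of freedom, so its higher count does not show a stronger response.

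**Figure D1:**
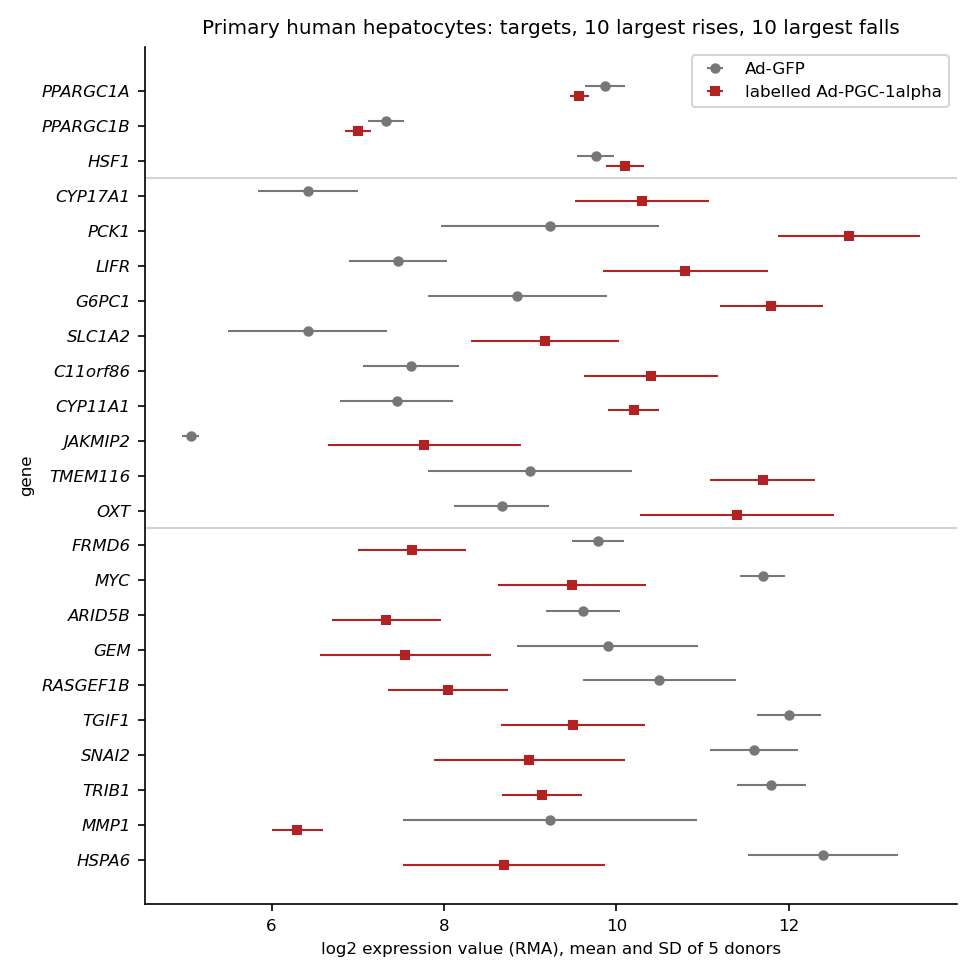
Mean log2 expression with SD over 5 donors for the target genes and for the 10 largest rises and 10 largest falls in primary hepatocytes, in grey for Ad-GFP and red for the arrays labelled Ad-PGC-1alpha. CYP17A1 lies at 6.42 and 10.3 and HSPA6 at 12.4 and 8.70, while PPARGC1A lies at 9.87 and 9.57.

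Genes of the mitochondrial respiratory chain rose together in hepatocytes. Of 34 measured genes of complex I, 31 rose and none fell, with a median of 0.82, and NDUFA8 and NDUFA5 stood highest at 1.55 (SE 0.24) and 1.31 (SE 0.21). Of 22 genes of complexes II to IV and cytochrome c, 19 rose, with a median of 0.77, among them CYCS, the cytochrome c gene, at 1.34, COX7B at 1.3 and SDHD at 1.26. Of 15 ATP synthase genes 13 rose, with a median of 0.67 and ATP5MC3 at 0.89. Of 19 genes of the citric acid cycle and pyruvate oxidation 13 rose, with a median of 0.82, led by IDH3A at 1.70, MPC1, a mitochondrial pyruvate carrier, at 1.56 and SUCLA2 at 1.38, while PDP1 at -1.29 passed only with the donor block (adjusted p = 0.295 without and 0.00223 with it), which gave 18 higher and 1 lower. Of 25 genes of fatty acid oxidation and ketogenesis 12 rose, and 19 with the block, with a median of 0.61, led by SLC25A20, the carnitine-acylcarnitine carrier, at 2.28 (SE 0.18), CPT1A at 1.85 and ETFDH at 1.82. Adjusted over the list alone, 33, 22, 13, 16 and 18 members of these 5 lists rose. The competitive list test of limma, camera, gave these lists in the same order adjusted p = 1.13e-22, 8.95e-18, 1.00e-09, 2.01e-10 and 1.76e-10. With an estimated correlation between genes none of these calls held, with adjusted p = 0.117, 0.117, 0.161, 0.182 and 0.117. An exact permutation test on the mean of each list, two-sided over 252 splits and added after seeing the data, gave adjusted p = 0.0317 for each of the 5, whose means were higher in 5 of 5 donors, complex I moving from 9.98 ± 0.14 to 10.8 ± 0.19 (SD, n = 5 each). That test leaves out the donor pairing, so its p does not hold exactly for these paired arrays.

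Other mitochondrial lists moved less in hepatocytes. Among 21 regulators of mitochondrial biogenesis 5 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone. GABPA, a transcription factor of nuclear mitochondrial genes, rose by 1.47, MFN2, a fusion protein, by 1.16 and PPARA, a fatty acid receptor, by 1.13, whereas PPRC1 changed by -1.12. That list had a median of 0.26 and a camera adjusted p = 0.0225, which became adjusted p = 0.537 with an estimated correlation and 0.061 with the donor block, and the exact permutation test on its mean, higher in 5 of 5 donors, gave adjusted p = 0.0847. Of 15 mitochondrial chaperones and proteases 3 rose, AFG3L2 by 0.96 and GRPEL1 by 0.91 among them, with 3 higher and 1 lower adjusted over the list alone, 4 and 1 with the donor block, a median of 0.19 and a camera adjusted p = 0.0832. Of 23 targets of PPAR alpha and the estrogen-related receptors 2 rose, also adjusted over the list alone, CYP1A1 by 1.90 and ESRRA, itself such a receptor, by 1.16, and 6 rose and 1 fell with the donor block, with a median of 0.13 and a camera adjusted p = 0.311.

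Heat shock chaperones fell together in hepatocytes. Of 28 measured members 22 fell and none rose, also when adjusted over the list alone, with a median of -0.92, and 23 fell and 1 rose with the donor block. After HSPA6 the largest changes were those of CHORDC1, a co-chaperone, at -2.05 (SE 0.22), DNAJA4 at -2.0 (SE 0.35) and DNAJB4 at -1.88 (SE 0.22). The list mean was 11.7 ± 0.15 after Ad-GFP and 10.7 ± 0.31 on the arrays labelled Ad-PGC-1alpha (SD, n = 5 each), lower in 5 of 5 donors. Camera gave adjusted p = 1.58e-15, which became adjusted p = 0.117 with an estimated correlation, and the exact permutation test on the list mean gave adjusted p = 0.0317. HSPA1A and HSPA1B share their human rows with other genes and are not reported here.

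Other protein folding lists in hepatocytes held fewer changes. Of 24 genes of the endoplasmic reticulum stress response 5 fell and 1 rose, with 8 and 1 adjusted over the list alone and 10 lower with the donor block. XBP1, a transcription factor of that response, changed by -1.20 and HERPUD1 by -0.92, while ATF4 rose by 0.49. The list had a median of -0.425 and a camera adjusted p = 0.000888, which became adjusted p = 0.161 with an estimated correlation. Its mean was lower in 5 of 5 donors, with a difference of -0.32 on average, and the exact permutation test on it gave adjusted p = 0.0317. Of 14 genes of the cytosolic chaperonin and prefoldin 3 fell, CCT6A by 0.67 and CCT2 by 0.62 among them, with 2 higher and 5 lower adjusted over the list alone, 3 and 5 with the donor block, a median of -0.15 and a camera adjusted p = 0.311. Of 28 proteasome genes 1 rose and 0 adjusted over the list alone, PSMD4 at 0.52 (limma adjusted p = 0.0498, and 0.0631 with a mean-variance trend), with 6 higher and 2 lower with the donor block, a median of 0.095 and a camera adjusted p = 0.477. In hepatocytes 3913 of all tested genes had an unadjusted limma p under 0.05.

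Lists of liver metabolism changed as single genes in hepatocytes. Of 15 genes of gluconeogenesis and glucose handling, PCK1 and G6PC1 rose and 2 fell, among them PFKFB3, a driver of glycolysis, at -1.31, with 3 higher and 2 lower adjusted over the list alone and 3 and 5 with the donor block. Its median was -0.048, its mean 0.165 and its camera direction down (adjusted p = 0.899). None of 16 glycolysis genes passed limma, over all genes or adjusted over the list alone, and their median of 0.011 and mean of 0.020 stood against a camera direction of down (adjusted p = 0.899). With the donor block 2 rose and 2 fell, among them PFKM, a phosphofructokinase, at 1.23 and SLC2A1, a glucose transporter, at -1.03. Of 17 cholesterol synthesis genes HMGCS1 alone fell, by 0.77, also adjusted over the list alone, and with the donor block 2 fell and 1 rose (median 0.062, camera adjusted p = 0.898). Of 21 genes of fatty acid and triglyceride synthesis 3 fell and 1 rose, with 3 and 2 adjusted over the list alone and 5 and 3 with the donor block, among them ACACA, an enzyme that commits carbon to fatty acids, at -0.92 and DGAT1 at 0.81 (median -0.175, camera adjusted p = 0.357). FASN stood at -0.72 and passed only with the donor block (adjusted p = 0.0958 without and 0.00493 with it). Of 18 bile acid genes 1 rose and 1 fell, with 2 and 1 adjusted over the list alone and 3 and 2 with the donor block, and NR0B2, a repressor of bile acid synthesis, rose by 2.28 (median 0.15, camera adjusted p = 0.64). Of 13 xenobiotic genes CYP1A2 rose by 2.39 and AHR, its regulator, changed by -1.08, also adjusted over the list alone, and with the donor block 5 rose and 1 fell (median 0.33, camera adjusted p = 0.64). Of 16 urea cycle and amino acid genes 1 rose, also adjusted over the list alone, with a median of -0.070 and a mean of -0.265 against a camera direction of up (adjusted p = 0.899), and CPS1 stood at -1.36 (adjusted p = 0.332, and 0.0497 with the donor block). Of 21 antioxidant genes 2 rose and 3 fell, with 2 and 4 adjusted over the list alone and 3 and 5 with the donor block, and TXNRD1, a thioredoxin reductase, and NFE2L2, its regulator, changed by -1.67 and -1.44. The antioxidant median was -0.013 with a camera adjusted p = 0.477, while the exact permutation test on its mean of -0.18 gave adjusted p = 0.0317.

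Lists of defence, growth and cell identity held few calls in hepatocytes. None of 25 interferon response genes passed limma, over all genes or adjusted over the list alone, with a median of -0.64 and a camera adjusted p = 0.129. With the donor block 7 of them fell and 1 rose, IFIT2, an antiviral protein, standing at -1.46 (adjusted p = 0.248 without and 0.0107 with it), and camera passed at adjusted p = 0.00638, which became adjusted p = 0.77 with an estimated correlation. Of 21 inflammation and acute phase genes 2 fell, also adjusted over the list alone, CXCL2, a neutrophil chemokine, by 1.53 among them, and with the donor block 6 fell and 2 rose (median -0.13, camera adjusted p = 0.205). None of 25 secreted hepatocyte proteins passed, also adjusted over the list alone, with a median of -0.0046, a mean of 0.11 and a camera direction of up (adjusted p = 0.898). With the donor block 6 of them rose and 0 fell, APOA4 and APOA5, apolipoproteins, at 1.85 and 1.37 and F10, a clotting factor, at 1.11 among them. Of 22 cell cycle genes AURKA, a mitotic kinase, alone rose, by 1.94, also adjusted over the list alone (median -0.24, camera adjusted p = 0.477), and with the donor block 2 rose and 3 fell. Of 16 p53 targets 3 fell and 1 rose, with 4 and 1 adjusted over the list alone and 7 lower with the donor block, GADD45A at -1.44 and TP53I3 at 0.89 among them (median -0.32, camera adjusted p = 0.093). None of 10 angiogenic factors passed, also adjusted over the list alone, with a median of 0.021, a mean of 0.0091 and a camera direction of down (adjusted p = 0.898), while GDF15 at -0.48 passed with the donor block. Among 11 hepatocyte identity factors 3 fell and none rose, with 4 adjusted over the list alone and 5 lower and 1 higher with the donor block, PROX1 at -1.01 and FOXA3 at -0.90, and the list had a median of -0.48. Its camera adjusted p = 0.00887 became adjusted p = 0.173 with an estimated correlation, and the exact permutation test on its mean, which does not use the pairing, gave adjusted p = 0.102. That mean was lower in 5 of 5 donors, with a difference of -0.43 (SD of the pair differences 0.12).

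Markers of other liver cell types had no call in hepatocytes without the donor block. No marker passed limma, over all genes or adjusted over the list alone, among 12 of macrophages (median -0.071, camera adjusted p = 0.898), 11 of stellate cells and fibroblasts (median 0.073, camera direction down, adjusted p = 0.996), 9 of cholangiocytes (median -0.29, camera adjusted p = 0.477) and 6 of lymphocytes (median 0.12, camera adjusted p = 0.477). The 10 endothelial markers had a median of -0.013, a mean of 0.067 and a camera direction of up (adjusted p = 0.898). With the donor block LYVE1, an endothelial marker, passed at 1.10 (adjusted p = 0.526 without and 0.00691 with it), as did RGS5 of the stellate list at 0.70 and CLDN4 and CD24 of the cholangiocyte list at -0.62 and -0.88. Within donors the mean of the lymphocyte list was higher in 5 of 5 pairs, by 0.15 (SD of the pair differences 0.021), and that of the cholangiocyte list lower in 5 of 5, at -0.29 (SD 0.26), while macrophage, endothelial and stellate means went both ways. With the donor block camera called none of these marker lists, with adjusted p = 0.303 for lymphocytes and 0.183 for cholangiocytes. Of the 32 lists camera called 9 in hepatocytes, 6 higher and 3 lower, and 0 held with an estimated correlation, where the smallest adjusted p was 0.117. The exact permutation test on list means called 8, 5 higher and 3 lower. Other divisions of the same 10 arrays called up to 22 lists, so the number of lists called by camera does not stand above that background. Of 74 named genes that passed, 27 lost their call when some donor pair was left out, ACACA, CCT2, CCT6A, DNAJA3, GEM, GPAM, PPRC1, PSMD4, PFKFB3, TP53I3 and AEN in at least 4 of the 5 cases, and 7 lost it under another alternative. For PPARGC1A, PVALB, HERPUD1, COX6C, FASN and IFIT2, 1 array of a virus lay far from the other 4. The hepatocytes came from separate donors. For HepG2 nothing says that the arrays came from separate cultures, so their p-values measure only the spread between these samples, which may be technical.

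**Figure D2:**
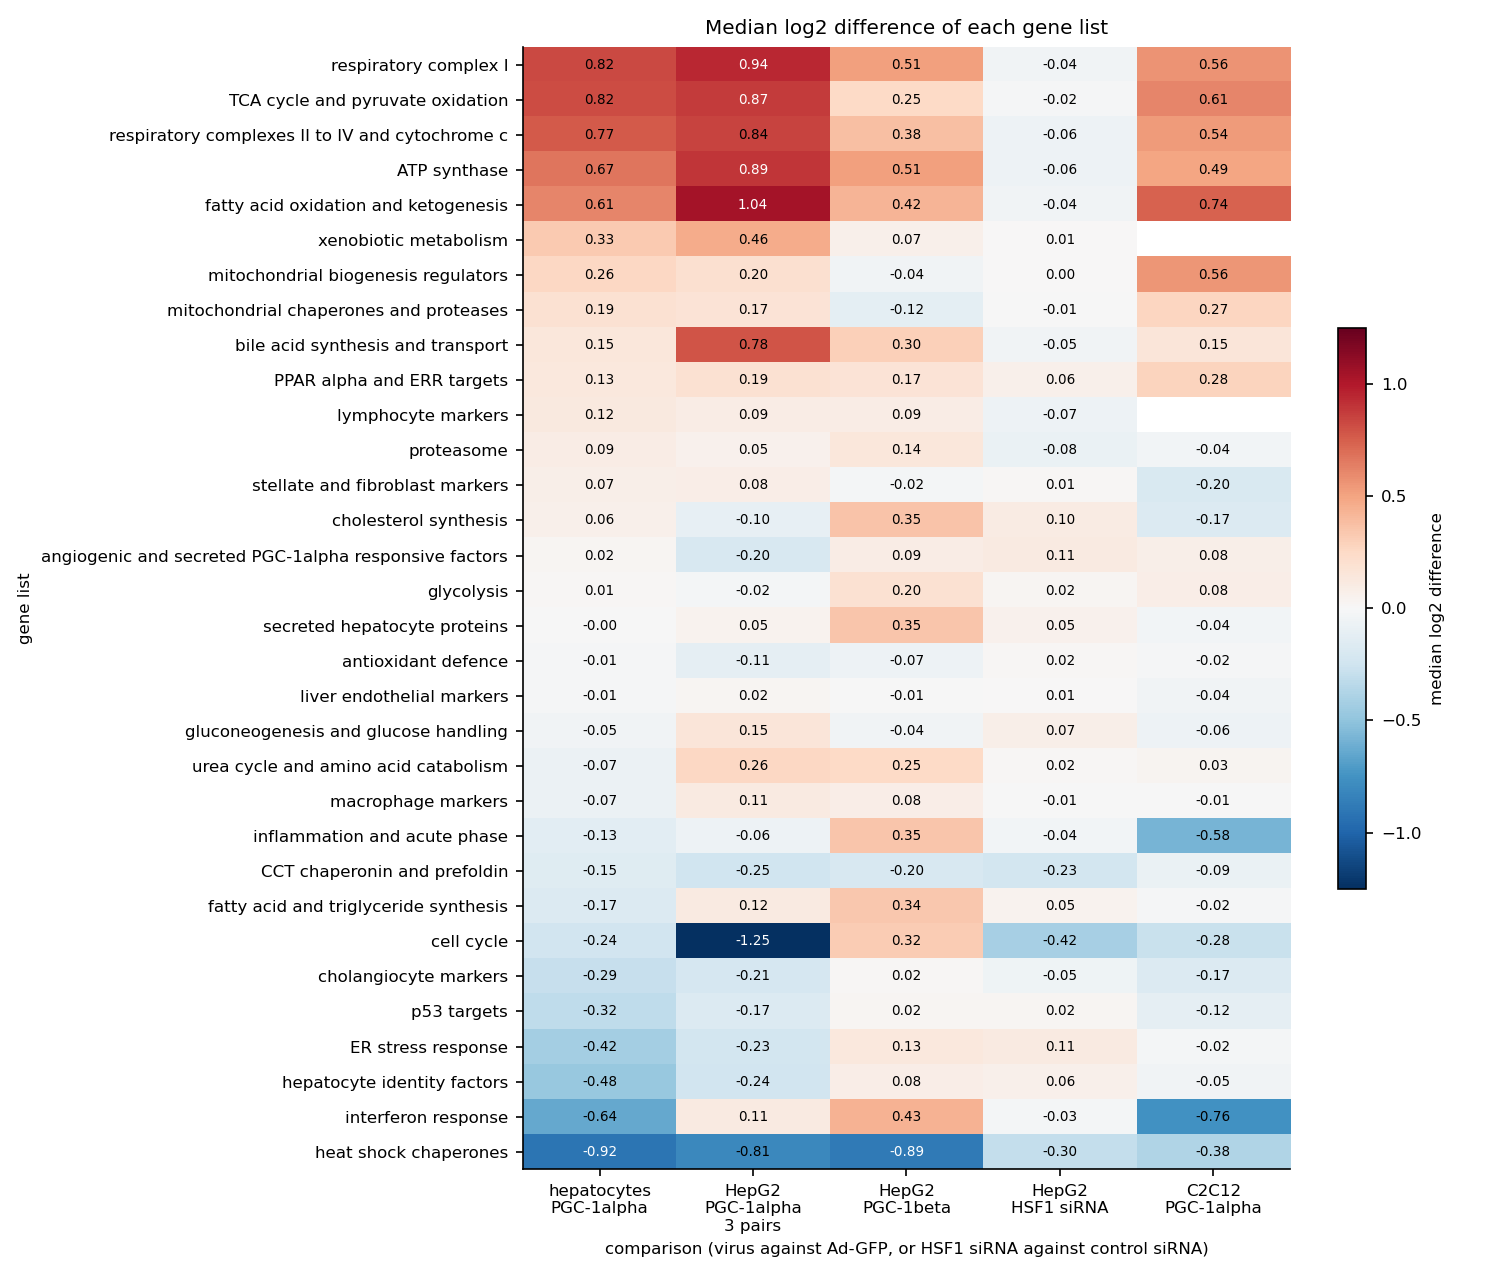
Median log2 difference of each gene list (colour and printed value) in 5 comparisons, with lists ordered by their hepatocyte median and blank cells for lists under 5 measured members. Complex I stands at 0.82 in hepatocytes, 0.94 in HepG2 and 0.56 in C2C12, and heat shock chaperones at -0.92, -0.81 and -0.38.

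HepG2 was compared over 3 pairs of arrays, without siRNA, with control siRNA and with HSF1 siRNA, to see whether a liver cancer line responds alike. DAO, which oxidises D-amino acids, had the largest rise at 4.86 (SE 0.09, n = 3 pairs, limma adjusted p = 8.19e-05). PGLYRP2, a secreted enzyme that cleaves bacterial cell wall, rose by 4.63 (SE 0.31), OLFML1 by 4.20 (SE 0.35), CYP17A1 by 4.04 (SE 0.73) and APOA4, an apolipoprotein, by 4.01 (SE 0.32). HSPA6 again had the largest fall, at -4.04 (SE 0.33, adjusted p = 0.000905), followed by KRT23, a keratin, at -3.98 (SE 0.11), SRGAP1 at -3.66 (SE 0.22), ANKRD1 at -3.44 (SE 0.45) and JAG1, a Notch ligand, at -3.32 (SE 0.32). All of these were chosen among genes that passed with the same sign in the 3 pairs. Of 15204 genes tested, 5742 passed, 2866 higher and 2876 lower (3012 and 2780 after median centring), and 1533 of them by at least 1 log2 unit. The count was 3505 without the siRNA state in the fit, and 2449 without the control siRNA pair.

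Genes of the respiratory chain, the citric acid cycle and fatty acid oxidation rose in HepG2 as well. Of 34 complex I genes 32 rose and none fell (median 0.94), NDUFB6 by 1.84 (SE 0.15) and NDUFB10 by 1.51 (SE 0.09) among them. Of 22 genes of complexes II to IV 21 rose (median 0.845), COX7B by 2.31 and SDHD by 1.68, and of 15 ATP synthase genes 13 rose (median 0.89), ATP5ME by 1.17. Of 19 citric acid cycle genes 17 rose and 1 fell (median 0.87), IDH3A by 2.05 and SUCLG1 by 1.85 upward and PDP1, a phosphatase that activates pyruvate dehydrogenase, at -1.44. Of 24 fatty acid oxidation genes 20 rose (median 1.04), SLC25A20 by 3.30 (SE 0.16) and ETFDH by 2.37 (SE 0.23). Adjusted over the list alone 33, 21, 14, 18 and 21 members of these lists rose and 1 citric acid cycle gene fell. Camera gave adjusted p = 3.62e-13, 2.72e-10, 1.76e-07, 5.07e-08 and 1.65e-08, none of which held with an estimated correlation (adjusted p = 0.547, 0.555, 0.536, 0.536 and 0.536). Of 21 biogenesis regulators 9 rose and 5 fell, 10 and 5 adjusted over the list alone, with PPARA at 1.92 and MFN2 at 1.45 (median 0.205, camera adjusted p = 0.349). Of 15 mitochondrial chaperones and proteases 5 rose and 1 fell, 5 and 2 adjusted over the list alone, with AFG3L2 at 0.78 and HTRA2 at 0.69 (median 0.17, camera adjusted p = 0.374). Of 22 PPAR alpha and ERR targets 8 rose and 4 fell, also adjusted over the list alone, with CREB3L3, a fasting-induced transcription factor, at 2.60, CIDEC at 2.25 and CYP1A1 at 2.18 (median 0.19, camera adjusted p = 0.152).

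Heat shock and cell cycle genes fell in HepG2. Of 28 heat shock chaperones 22 fell and none rose, 23 adjusted over the list alone (median -0.81), with CRYAB, a small heat shock protein, at -3.08 (SE 0.51), DNAJB4 at -2.69 (SE 0.11) and CHORDC1 at -1.97 (SE 0.10). Of 26 cell cycle genes 24 fell and AURKA rose, also adjusted over the list alone (median -1.25), with CDK1, the mitotic kinase, at -1.83, MCM6, a part of the replicative helicase, at -1.75 and BUB1B at -1.66. Camera gave adjusted p = 2.82e-11 and 2.09e-11, and with an estimated correlation adjusted p = 0.527 and 0.536. For the heat shock list the estimate was 0.00185, below the preset 0.01, so a higher correlation does not account for its lost call. The form with an estimated correlation rests on the 2 residual degrees of freedom of this fit, which raises its p-values. Of 24 endoplasmic reticulum stress genes 7 fell, also adjusted over the list alone, with ATF3 at -1.24 and XBP1 at -1.07 (median -0.23, camera adjusted p = 0.0125, and adjusted p = 0.536 with an estimated correlation). Of 14 chaperonin genes 6 fell and 1 rose, 7 and 2 adjusted over the list alone, with CCT2 at -0.79 (median -0.25, camera adjusted p = 0.119). Of 28 proteasome genes 2 rose and 1 fell, 0 and 1 adjusted over the list alone, PSMD14 at -0.70 (median 0.050, camera adjusted p = 0.758). Of 16 p53 targets 7 fell and 2 rose, 7 and 4 adjusted over the list alone, with PLK3 at -1.19 (median -0.175, camera adjusted p = 0.152). CRYAB did not pass without the control siRNA pair (adjusted p = 0.0752) or without the siRNA state in the fit (0.0772).

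Bile acid genes rose in HepG2, 11 of 17 with 1 lower, and 12 and 1 adjusted over the list alone (median 0.78). CYP7A1, the rate-limiting enzyme of bile acid synthesis, rose by 3.5 (SE 0.23), CYP8B1 by 1.97 and NR0B2 by 1.74. The camera adjusted p = 0.00108 became adjusted p = 0.536 with an estimated correlation. Of 15 urea cycle and amino acid genes 6 rose and 1 fell, 7 and 1 adjusted over the list alone, with ASS1 at 1.49 and ARG1, the arginase gene, at -1.18, which did not pass without the siRNA state in the fit (median 0.26, camera adjusted p = 0.0439, and adjusted p = 0.536 with an estimated correlation). Of 14 glucose handling genes 3 rose and 4 fell, 6 and 5 adjusted over the list alone, with PFKFB3 at -2.40 and G6PC1 at 2.12, a median of 0.155, a mean of -0.15 and a camera direction of down (adjusted p = 0.841). Of 16 glycolysis genes 4 fell and 1 rose, also adjusted over the list alone, with PFKP at -1.22 and ENO2 at -1.19 (median -0.024, camera adjusted p = 0.374). Of 17 cholesterol synthesis genes 3 fell and 1 rose, 2 and 1 adjusted over the list alone, NSDHL at 0.58 (median -0.10, camera adjusted p = 0.292). Of 20 fatty acid and triglyceride synthesis genes 7 rose and 8 fell, also adjusted over the list alone, FASN at -1.33 and LPIN1 at 1.03, with a median of 0.115, a mean of -0.11 and a camera direction of down (adjusted p = 0.88). Of 10 xenobiotic genes 5 rose and 1 fell, 6 and 2 adjusted over the list alone, with NR1I3, a xenobiotic receptor, at 2.24 and AHR at -1.73 (median 0.46, camera adjusted p = 0.152).

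Of 21 antioxidant genes 8 fell and 5 rose in HepG2, also adjusted over the list alone, with TXNRD1 at -3.02 (SE 0.20), GCLM and GCLC, which make glutathione, at -2.74 and -1.94, and NFE2L2 at -1.44 (median -0.11, camera adjusted p = 0.349). Of 21 interferon genes 9 rose and 3 fell, also adjusted over the list alone, with IFIH1, an RNA sensor, at 2.27 (median 0.11, camera adjusted p = 0.267). Of 19 inflammation genes 5 fell, 4 adjusted over the list alone, with CXCL8, a chemokine, at -2.99 and HAMP, the hepcidin gene, at -2.63 (median -0.063, camera adjusted p = 0.152). Of 24 secreted hepatocyte proteins 9 rose and 1 fell, also adjusted over the list alone, with APOA5 at 1.64 (median 0.046, camera adjusted p = 0.174). Among 11 identity factors 5 fell, also adjusted over the list alone, with FOXA1 at -1.92 (median -0.24, camera adjusted p = 0.0282, and adjusted p = 0.584 with an estimated correlation). Of 9 angiogenic factors 1 rose and 2 fell, also adjusted over the list alone, with FNDC5 at 1.47 (median -0.20, camera adjusted p = 0.38). Among cell type markers, 3 of 9 cholangiocyte genes fell, also adjusted over the list alone, with CD24 at -2.07 and KRT19 at -2.03 (median -0.21, camera adjusted p = 0.0282, and adjusted p = 0.584 with an estimated correlation). Of 10 endothelial markers 2 rose, also adjusted over the list alone, CDH5 at 1.36 (median 0.022, camera adjusted p = 0.447). Of 10 macrophage and 6 lymphocyte markers 1 each rose over all genes and 0 adjusted over the list alone (medians 0.11 and 0.090, camera adjusted p = 0.374 and 0.86), and of 11 stellate markers 1 rose and 1 fell, also adjusted over the list alone, ACTA2 at -0.75 (median 0.079, camera adjusted p = 0.841). In HepG2 7052 of the 15204 genes had an unadjusted limma p under 0.05. Camera called 12 of the 32 lists, 7 higher and 5 lower, and 0 with an estimated correlation. The fry test, which asks whether a list moves one way without comparing it with other genes, called 20, among them 11 of these 12 but not the cholangiocyte list (adjusted p = 0.0915). Of 122 named genes that passed, 28 lost their call when a pair was left out, nearly always the control siRNA pair, and 15 without the siRNA state in the fit.

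HSF1 siRNA was compared with control siRNA under both viruses to see which HepG2 genes differ when HSF1 is lowered. CRYAB differed by -2.68 under Ad-GFP and -0.535 on the arrays labelled Ad-PGC-1alpha, HSPB1, a small heat shock protein, by -0.84 and -0.94, PNRC2 by -0.82 and -0.955, and FAM111B by -0.84 and -0.92. Higher under both viruses were ARRDC4 by 1.91 and 0.86, CXCL8 by 2.15 and 0.59, BRINP2 by 2.61 and 0.12, SNAI2 by 2.19 and 0.285 and SERPINB8 by 1.84 and 0.58. In the fit over 6 arrays 0 of 15204 genes passed limma, with 664 at an unadjusted p under 0.05, and HSF1 itself stood at -1.16. In a fit of the 4 siRNA arrays alone 9 genes passed, HSF1 at -1.16, HSPB1, FAM111B and PNRC2 lower, and CTH and SLC7A11, which serve cysteine supply, CHGB, GPAT3 and DNAAF11 higher. Their adjusted p lay between 0.0404 and 0.0448 by limma, in a fit that leaves few residual degrees of freedom.

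Heat shock chaperones and cell cycle genes were lower as lists after HSF1 siRNA. The 28 heat shock genes had a median of -0.30, with 7 lower adjusted over the list alone and 0 over all genes, and HSPH1 stood at -0.69 and CACYBP at -0.66 beside CRYAB at -1.61. The 26 cell cycle genes had a median of -0.42, with 12 lower adjusted over the list alone, TOP2A at -0.80 and MCM3 at -0.70. The 14 chaperonin genes had a median of -0.23, with CCT6A at -0.39 and CCT3 at -0.375, and the 24 endoplasmic reticulum stress genes a median of 0.11, with ASNS at 0.38 and DDIT3 at 0.35, none adjusted over the list alone. Camera gave these 4 lists adjusted p = 1.26e-14, 1.73e-20, 0.000151 and 0.00821, none of which held with an estimated correlation (adjusted p = 0.399, 0.663, 0.861 and 0.852). The estimates for the heat shock and endoplasmic reticulum stress lists, 0.00185 and 0.00872, lay below the preset 0.01. A higher correlation therefore does not account for the lost calls of those lists. The form with an estimated correlation rests on 2 residual degrees of freedom here as well. Fry called none of the 32 lists either, with a smallest adjusted p of 0.451. Under Ad-GFP and on the arrays labelled Ad-PGC-1alpha the medians were -0.38 and -0.21 for heat shock genes and -0.48 and -0.37 for cell cycle genes. The other 28 lists had camera adjusted p between 0.0608 and 0.964, among them the mitochondrial lists, whose medians lay at -0.042 for complex I and -0.044 for fatty acid oxidation, and of their genes 1 higher and 1 lower, in the urea cycle list, passed adjusted over the list alone. Median and camera direction differed in sign for inflammation genes, at -0.036 with a mean of 0.029 and direction up, and for the urea cycle list, at 0.016 with a mean of -0.021 and direction down. The mean alone had the other sign for macrophage markers, at 0.0024 with a median of -0.0078, and for stellate markers, at -0.012 with a median of 0.013.

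The pairs with siRNA showed how far the difference between viruses went with HSF1 lowered. The HSF1 row stood at -1.16 after its siRNA and still read 8.82 under Ad-GFP, so the transcript was lowered only in part. A virus difference that stayed in that pair therefore does not show that it is independent of HSF1. Among 2387 genes that differed by at least 1 log2 unit in the pair without siRNA, the 1168 higher ones had medians of 0.93 with control siRNA and 0.98 with HSF1 siRNA, and the 1219 lower ones -0.96 and -0.83. The slope of the HSF1 siRNA pair on the control siRNA pair was 0.954 (SE 0.0065 across genes, which are not independent replicates), and 2326 genes kept their sign in both pairs. The heat shock list had medians of -0.91, -0.85 and -0.73 without siRNA, with control siRNA and with HSF1 siRNA. HSPA6 differed by -4.87, -4.22 and -3.04 in that order and CRYAB by -4.29, -3.55 and -1.41, whereas HSPH1 differed by -0.93, -1.75 and -2.39. After Ad-GFP HSPA6 read 13.6, 12.7 and 11.5 and CRYAB 11.9, 10.1 and 7.41. On the arrays labelled Ad-PGC-1alpha HSPA6 read 8.69, 8.45 and 8.42 and CRYAB 7.56, 6.54 and 6.0. The 30th percentile of the last of these arrays was 5.64. The smaller differences of HSPA6 and CRYAB thus came with lower Ad-GFP values, and do not show a weaker effect of the virus. The list's median change from control to HSF1 siRNA was 0.098, at the 96.4 percentile of 10000 random lists of matched level. Complex I had medians of 1.06, 0.84 and 0.92, and cell cycle genes -0.92, -1.27 and -1.20. Each pair is 1 array per virus, so these differences have no replicate check.

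**Figure D3:**
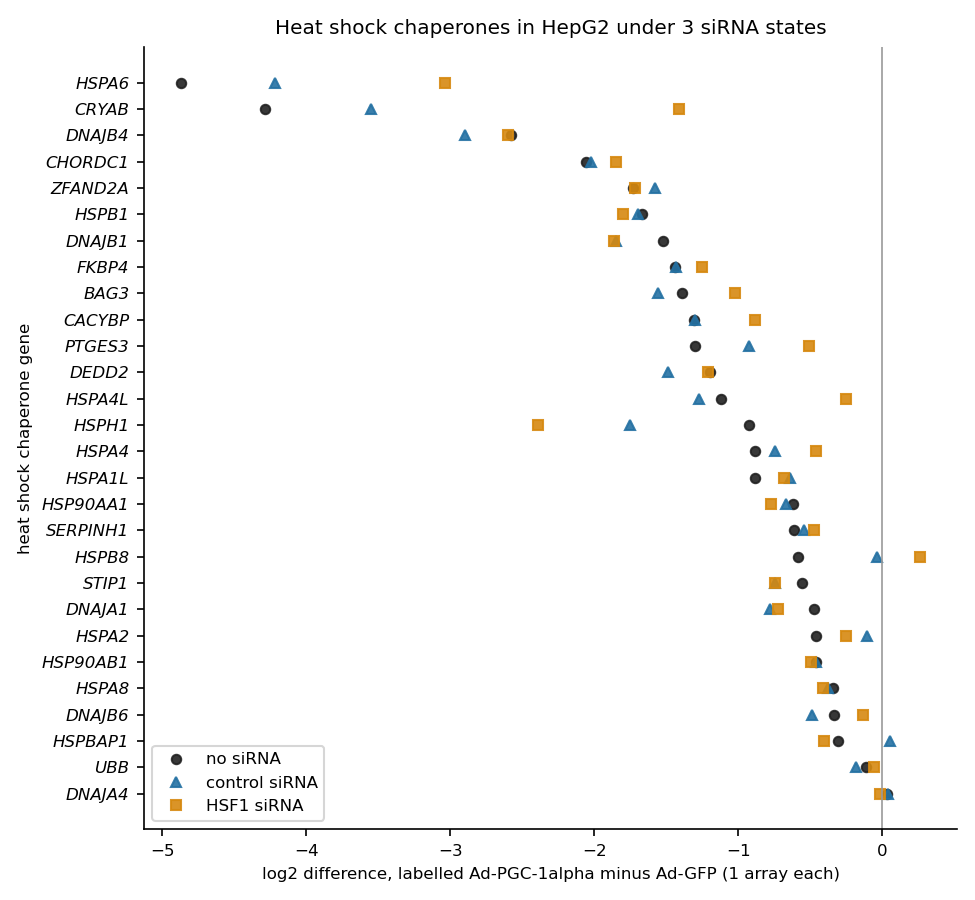
Log2 difference of the arrays labelled Ad-PGC-1alpha from Ad-GFP for each of 28 heat shock chaperones in HepG2 without siRNA (circles), with control siRNA (triangles) and with HSF1 siRNA (squares), 1 array per point and virus. HSPA6 runs from -4.87 to -3.04 and CRYAB from -4.29 to -1.41. Their Ad-GFP values fall from 13.6 to 11.5 and from 11.9 to 7.41 over the same arrays.

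**Figure D4:**
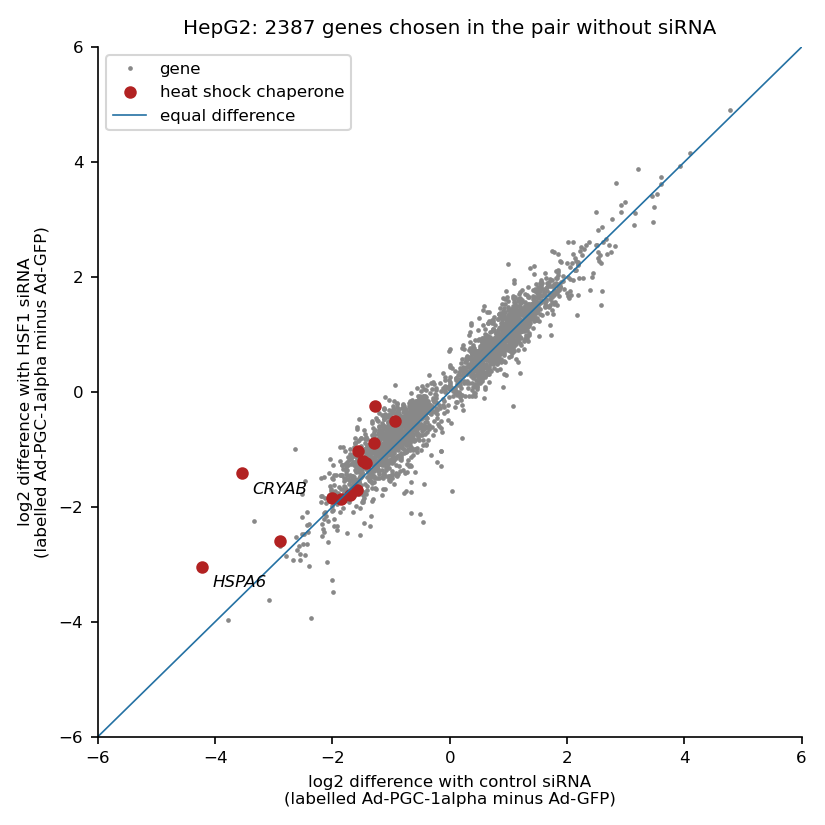
Log2 difference of the arrays labelled Ad-PGC-1alpha from Ad-GFP with control siRNA (horizontal) and HSF1 siRNA (vertical) for 2387 HepG2 genes chosen in the pair without siRNA, with heat shock chaperones in red and a line of equal difference. The points follow the line with a slope of 0.954.

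The array labelled Ad-PGC-1beta was set against Ad-GFP and against the array labelled Ad-PGC-1alpha in HepG2 to compare the related coactivators, with 1 array each. HSPA6 differed from its value after Ad-GFP by -5.97, CRYAB by -3.04, CYP24A1, which inactivates vitamin D, by -2.87, CCN1 by -2.62 and SRGAP1 by -2.55. CCL5, a chemokine, was higher by 2.43, IFIT1 and IFIT2, antiviral proteins, by 2.38 and 1.52, H2AC15 by 1.51 and FBXO16 by 1.5. At least 1 log2 unit separated 326 of 11718 genes from Ad-GFP, 79 higher and 247 lower, against 2351 of 11842 for the array labelled Ad-PGC-1alpha. For the arrays labelled Ad-PGC-1alpha the count was 1349 of 11905 with control siRNA and 1312 of 11868 with HSF1 siRNA. Neither coactivator's row was higher on its array without siRNA, so these counts do not compare the coactivators at equal amounts. Against the array labelled Ad-PGC-1alpha, LGR5, a stem cell receptor, was higher by 3.75, SLC6A14 by 3.60, HAMP by 3.56, FLRT3 by 3.54 and H2BC14 by 3.51, while CYP17A1 differed by -5.69, PGLYRP2 by -5.48, ATP4A by -5.43, TRIM31 by -5.20 and RRAGD by -4.86.

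Heat shock chaperones had a median of -0.89 on the array labelled Ad-PGC-1beta, with 27 of 28 below Ad-GFP, and lay below all of 10000 random lists of matched level. Chaperonin genes had a median of -0.20 (percentile 0.66). Complex I genes had a median of 0.51, ATP synthase genes 0.51, complexes II to IV 0.38 and fatty acid oxidation 0.42, each at or above the percentile 99.98, and the citric acid cycle 0.25 (percentile 96.0). Interferon genes stood at 0.43, above the random lists, cholesterol synthesis at 0.355, secreted proteins at 0.35, inflammation at 0.35, fatty acid synthesis at 0.335, cell cycle at 0.32 and bile acid genes at 0.30, each above the percentile 99.8. Urea cycle genes stood at 0.25 (percentile 98.6) and PPAR alpha targets at 0.17 (percentile 97.8), and the remaining lists lay between the percentiles 4.24 and 87.1, the mitochondrial chaperones lowest at -0.12. Against the array labelled Ad-PGC-1alpha, cell cycle genes were higher with a median of 1.03, above the random lists, and identity factors with 0.78, while fatty acid oxidation genes had a median of -0.685 and complex I genes -0.55 (percentile 0.01). Across 15204 genes the differences of both viruses from the shared Ad-GFP array correlated at 0.379 (SE 0.0104 over genes), while unchanged arrays simulated against that shared array gave 0.501. The simulated correlation follows from equal noise in every array whatever the data, so it is no scale for the observed one. The covariance was 0.113, the simulated one 0.0255 and their difference 0.0879, and part of the excess may come from the shared control. Against the control siRNA pair, which shares no array, the correlation was 0.339 and the covariance 0.0769, so a positive relation remained without a shared array. Of 574 genes at least 1 log2 unit higher in that pair, 438 were above 0 on the array labelled Ad-PGC-1beta, with a median of 0.28 against 1.62 for the array labelled Ad-PGC-1alpha without siRNA, and of 800 lower ones 564 were below 0, with medians of -0.29 and -1.37.

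C2C12 myotubes were compared to extend the question to muscle, with 1 array per virus and no replicate check. Beside Ppargc1a at 4.82, Nppb, a natriuretic peptide gene, was higher by 4.72, Cdk15 by 4.49, Rpp25 by 3.97, Elovl7, a fatty acid elongase, by 3.97, Bdh1, an enzyme of ketone metabolism, by 3.65, Hpdl by 3.57, Fdx1, a mitochondrial ferredoxin, by 3.52, Ndst3 by 2.95 and Psca by 2.90. Saa3, an acute phase gene, differed by -3.99, Hspa1a, a stress-induced chaperone, by -3.21, Il6 by -2.46, Prg4 by -2.14, Il33 by -2.13, Ccl2 by -2.06, Cxcl5 by -2.01, Nos2 by -2.01, Steap4 by -1.94 and Gbp2b by -1.72. Ppargc1b stood at -0.65. Of 12023 genes 522 differed by at least 1 log2 unit, 389 higher and 133 lower.

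Lists of the respiratory chain, citric acid cycle, fatty acid oxidation and mitochondrial biogenesis were higher in C2C12 than all 10000 random lists of matched level. The medians were 0.74 for fatty acid oxidation, 0.61 for the citric acid cycle, 0.56 for complex I with 35 of 35 genes above 0, 0.555 for biogenesis regulators, 0.54 for complexes II to IV and 0.49 for ATP synthase. Ppara stood at 2.35, Sirt3, a mitochondrial deacetylase, at 1.59, Idh3a at 1.54, Ndufb10 at 1.50, Etfdh at 1.41, Slc25a20 at 1.39 and Sdhd at 1.15. PPAR alpha and ERR targets had a median of 0.28 (percentile 99.99), with Ckmt2 at 2.19, Pdk4, a brake on pyruvate oxidation, at 1.92 and Esrra at 1.74, mitochondrial chaperones 0.27 (percentile 99.3) and bile acid genes 0.15 (percentile 99.2). Interferon genes had a median of -0.76, with Cxcl10 at -1.57, inflammation genes -0.58 and heat shock chaperones -0.375, with Hsph1 at -0.96, each below all random lists. Cell cycle genes stood at -0.28 (percentile 0.125), myoblast markers at -0.25 (percentile 0.77), stellate and fibroblast markers at -0.195 (percentile 2.86) with Dcn at -1.56, and cholesterol synthesis at -0.17 (percentile 3.67). Muscle contractile genes stood at -0.074 (percentile 23.0), with Myl2, a slow muscle light chain, at 1.56. The remaining lists lay between the percentiles 7.07 and 87.8, with Trib3 and Ddit3 of the endoplasmic reticulum stress list at 1.80 and 1.39 and Vegfa of the angiogenic list at 0.93, and xenobiotic and lymphocyte genes were too few to compare.

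**Figure D5:**
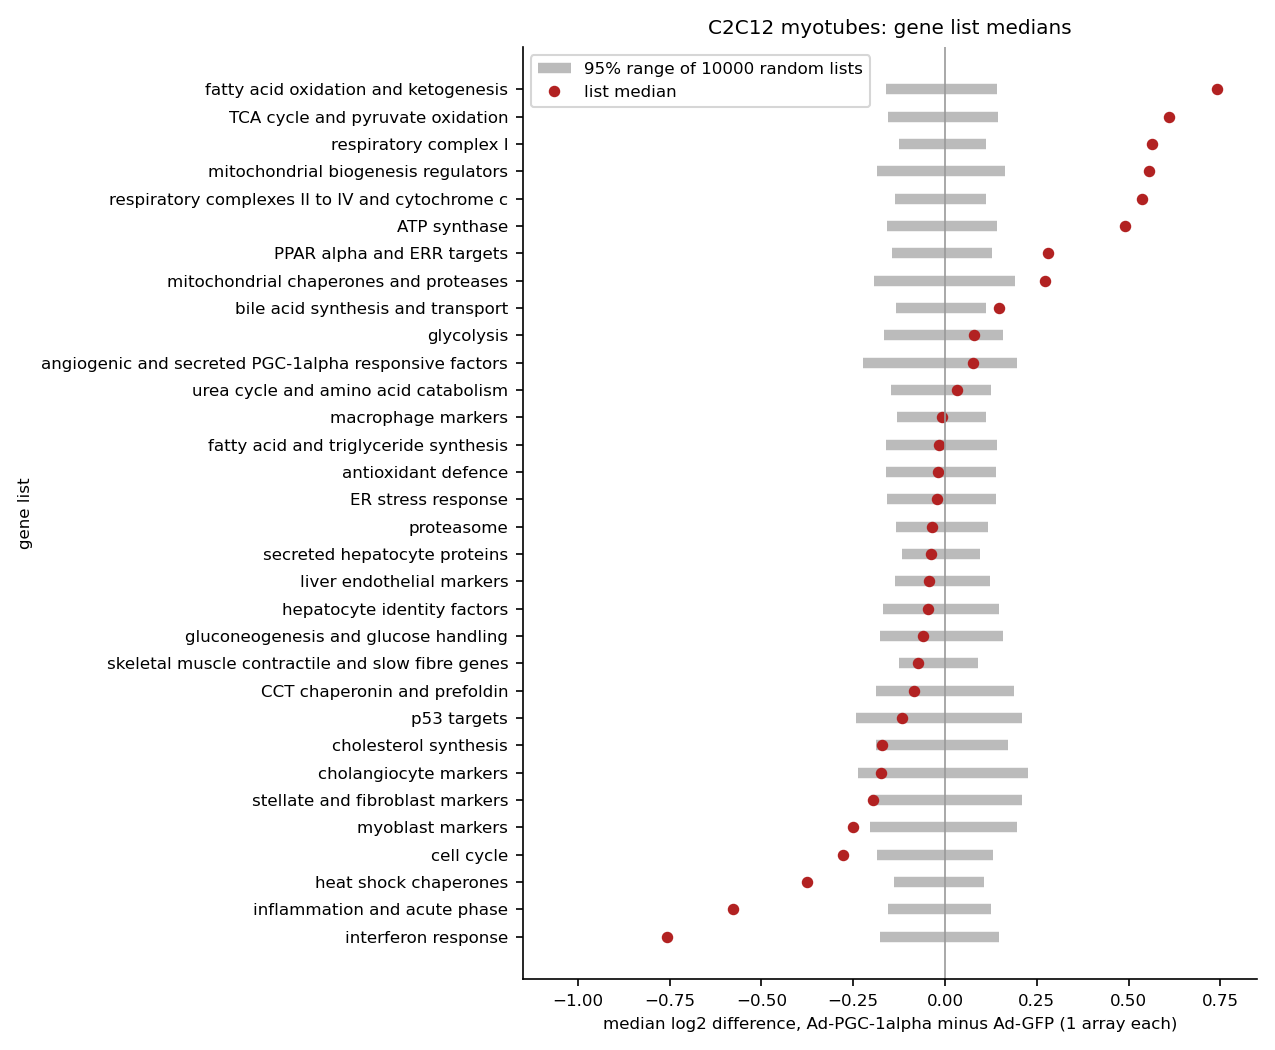
Median log2 difference of each gene list in C2C12 myotubes between 1 Ad-PGC-1alpha and 1 Ad-GFP array (red), with the 95% range of 10000 random lists of matched level (grey). Fatty acid oxidation at 0.74 and interferon response at -0.76 lie furthest from their ranges.

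The difference between viruses was itself compared between hepatocytes and HepG2, over 5 donor pairs and 3 HepG2 pairs. CYP24A1 stood at 0.75 in hepatocytes and -3.09 in HepG2, a difference of 3.84 (SE 0.37, limma adjusted p = 0.00271), KRTAP3-1 differed by 2.83, KRT23 by 2.63, LGR5 by 2.57 and DYNLT5 by 2.48. MMP20 stood at 0.20 and 3.90, a difference of -3.70, NPY6R differed by -3.68, DAO by -3.61, HTR3B, a serotonin receptor subunit, by -3.33 and TMT1B by -3.12. In hepatocytes HTR3B stood at 0.0057, LGR5 at 0.012, KRTAP3-1 at 0.093 and NPY6R at 0.19. There KRT23 stood at -1.35, TMT1B at -0.61, DAO at 1.24 and DYNLT5 at 2.54. Genes needed a signal in only 3 of 16 arrays, so a gene silent in hepatocytes could differ here for that reason. Of 16148 genes 671 passed, 279 with the higher value in hepatocytes and 392 with the lower, and 3116 had an unadjusted p under 0.05. Without the pairing 82 genes passed, and KRT23, NPY6R, DAO and TMT1B did not (adjusted p = 0.829, 0.0844, 0.419 and 0.0629). With a mean-variance trend KRT23 and DAO did not pass either (adjusted p = 0.0596 and 0.128). Without the HSF1 siRNA pair 249 genes passed.

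Cell cycle genes differed between the cells with a median of 0.89, as 6 of 26 passed with the higher value in hepatocytes, 21 adjusted over the list alone. Interferon genes had a median of -0.66, with 3 of 25 lower in hepatocytes and 4 adjusted over the list alone, urea cycle genes -0.56, with 2 of 16 and 3, and fatty acid oxidation genes -0.325, with 1 of 25 and 5. Camera gave adjusted p = 1.02e-13, 3.18e-05, 0.0236 and 0.0418, and with an estimated correlation adjusted p = 0.86 for each. With fry 0 lists passed, with a smallest adjusted p of 0.104. The heat shock list differed by a median of 0.097 (camera adjusted p = 0.371), with 2 genes higher in hepatocytes and 1 lower, 3 and 2 adjusted over the list alone, and complex I by -0.065 with none of 34 passing limma, also adjusted over the list alone. The 28 lists without a call had camera adjusted p between 0.0799 and 0.946. Other divisions of the 8 pairs called up to 17 lists, so the 4 lists called here do not stand above that background. Across 14725 genes the log2 changes of both human cells correlated at 0.70. Genes called in both rose together in 692 cases, where independent lists of 822 and 2820 would share 157.0, and fell together in 709, where lists of 893 and 2767 would share 168.0, with 12 opposite calls. Of 704 genes that rose in hepatocytes and were measured in C2C12, 574 were higher there (81.5%), and of 806 that fell 638 were lower (79.2%), while 47.0% of all 11936 genes were higher, with a correlation of 0.382 across genes.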

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

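The counts over other divisions of the arrays were planned, while all tests that weigh the 3 patterns in this part were chosen only after the result was seen. In hepatocytes the 1771 genes stood above every other of 100 divisions of the 10 arrays (1 of 100 as large, highest other 1085). Most of these divisions keep some donor pairs together, which the real one does not. Only the 16 divisions that part every pair keep to the pairing, too few to exclude chance at a share under 0.05. The division with 1085 genes kept 4 of the 5 donor pairs together, and among 13 others that part all 5 pairs, as the real one does, the highest was 0. For the 9 lists called by camera, 74 of 100 divisions called as many and the highest called 22, which does not exclude chance. Whether that comes from a structure of the samples or from the preset correlation of 0.01, below the 0.0614 to 0.461 estimated for these 9 lists, was not tested. With the donor block 1 of 16 divisions, the real one, called 4262 genes and the highest other 0, and 16 are too few for a share under 0.05. In HepG2 the real division gave 5742 genes against a highest other of 0, and 12 lists against 11, and with 1 of 10 divisions as large the 10 are too few as well. For the difference between hepatocytes and HepG2 the 671 genes exceeded the highest other of 144 (1 of 56 divisions as large). These divisions treat all pairs as alike units, while the HepG2 pairs come from a single cell line and may resemble each other for that reason. The count cannot tell a difference between the kinds of cell from that likeness, so chance is not excluded. At least the 4 lists were called in 51 of 56 divisions and the highest called 17, which does not exclude chance, and the cause was not tested.

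The PPARGC1A row differed by -0.30 in hepatocytes and by -0.105, -0.131 and 0.012 in the HepG2 pairs, and passed as higher in neither. An exchange of the labels in hepatocytes is argued against, since the complex I list had a median of 0.821 there, the same direction as in C2C12, where the Ppargc1a row was higher. Saturation is argued against, as the row lay at most at the 86.3 percentile of an Ad-GFP array. A candidate explanation that stays open is that the row does not match the transcript carried by the virus, as the mouse row, with other probes, was higher by 4.82 in C2C12. The sequences of the probes and of the virus were not used here, so this remains a hypothesis.

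Heat shock chaperones were lower on the arrays labelled Ad-PGC-1alpha in hepatocytes and HepG2. A lower HSF1 transcript is argued against, as the HSF1 row differed by 0.373 and was higher in 5 of 5 donor pairs. Heat shock genes raised in the Ad-GFP arrays may account for part of the pattern, because the list was also below Ad-GFP on the array labelled Ad-PGC-1beta (median -0.887), although a related coactivator with the same effect would give that too. Lower HSF1 activity is a second open explanation, as across the 28 members the HSF1 siRNA difference under Ad-GFP and the virus difference of the pair without siRNA, which share no array, ranked together with a Spearman rho of 0.662, above the upper end of the central 95% of random lists (0.371), while over all genes rho was -0.0157. No uninfected cells were analysed here, so both stay open.

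The cell cycle list fell in HepG2 and had no call in hepatocytes. Levels near the floor in hepatocytes are argued against as the whole cause, since 16 members at or above the 50th percentile there had a median of -0.306 in hepatocytes and -1.01 in HepG2, with a median difference of 0.792 and an interquartile range of 0.661 to 1.05. Differences in donor level that hide a fall of about 1 log2 unit are argued against, as 3 of 22 members fell with the donor block. That fit recovered 91.5% of simulated changes of 1 log2 unit but 0% of changes of 0.5. A smaller fall, or one that differs between donors, cannot be decided by that count. The list mean was lower in 3 donor pairs and higher in 2, at -0.138 (SD of the pair differences 0.375). The lower starting level in hepatocytes (list median 7.71 against 9.83 in HepG2, both after Ad-GFP) and the growth state of the cells stay open, the latter untested.

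Within the hepatocyte groups, 11 of 310 sets of 5 arrays held a value far from the other 4 by the ratio of its gap to the whole range. Chance flags about 1 in 20 groups, or 15.5 here. After Ad-GFP a single high value stood apart for CCL5 (ratio 0.857), PPARGC1A (0.769), ACTA2 (0.754), PVALB and IFIH1 (both 0.748) and PDGFRB (0.746), and a low one for FASN (0.721). On the arrays labelled Ad-PGC-1alpha a high value stood apart for HERPUD1 (0.786), COX6C (0.768) and IFIT2 (0.726) and a low one for HMOX1 (0.741).

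The difference between viruses itself differed between hepatocytes and HepG2 for 671 genes by limma. A gene silent in hepatocytes could pass the filter of this comparison and differ for that reason. It was higher in hepatocytes by 3.84 for CYP24A1, 2.83 for KRTAP3-1, 2.63 for KRT23, 2.57 for LGR5 and 2.48 for DYNLT5. It differed the other way by -3.70 for MMP20, -3.68 for NPY6R, -3.61 for DAO, -3.33 for HTR3B and -3.12 for TMT1B. Rows without a single gene symbol, which no comparison used, also differed between the viruses in hepatocytes, 144 of 7135 tested, 70 higher and 74 lower. Of these 56 listed several symbols and 88 were not listed with a gene.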

How the results depend on the processing

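The fits within donor sets, the list tests without a HepG2 pair, fry outside hepatocytes and the list tests on 4 siRNA arrays were chosen only after the result was seen, and all other tests here were planned. Across filters, normalizations, a mean-variance trend and every row of a gene, hepatocyte counts lay between 1677 and 1865 genes, HepG2 counts between 5492 and 5792, and counts for the difference between the cells between 653 and 674. RMA had already quantile normalized the deposited values, so normalizing them again is a weak check of that step. No named gene that passed changed its sign, but median centring turned the balance of calls to 953 higher and 829 lower in hepatocytes (839 and 932 without it) and to 3012 and 2780 in HepG2 (2866 and 2876). The donor block gave 4262 genes in hepatocytes, and as a random block 4655. It ended the list call of mitochondrial biogenesis (adjusted p = 0.061), added that of interferon (adjusted p = 0.00638), gained the single genes named with it and the members counted beside each list, and changed no other list call by camera. Without 1 replicate the hepatocyte count lay between 753 and 1619, and with the block between 2832 and 3679, where fewer samples leave less power. Within the sets of 3 and 2 donors the block gave 3313 and 5821 genes. The set of 2 donors leaves few residual degrees of freedom, so its count does not show a stronger response, and the cause was not tested. At least 1 log2 unit was reached by 649 genes in hepatocytes and 1533 in HepG2. An estimated correlation gave 0 lists in hepatocytes, 0 in HepG2 and 0 after HSF1 siRNA. For heat shock chaperones in HepG2 the estimate was 0.00185, below the preset 0.01. Yet the camera adjusted p went from 2.82e-11 to 0.527 for the virus and from 1.26e-14 to 0.399 for HSF1 siRNA. A higher correlation between genes thus does not account for these losses. With an estimated correlation camera uses the 2 residual degrees of freedom of this fit, which the preset form does not. That raises its p-values, so a lost call there says little about whether a list moved. By fry 9 lists were called in hepatocytes, 20 in HepG2 (camera 12) and 0 after HSF1 siRNA (smallest adjusted p = 0.451). Between the cells fry called 0 (smallest adjusted p = 0.104), and the cause was not tested. Without 1 pair HepG2 gave between 2449 and 6157 genes, the lowest without the control siRNA pair, and without the siRNA state 3505, where differences between states enter the residual. The lists called numbered between 9 and 11 without 1 replicate in hepatocytes and between 9 and 12 without 1 pair in HepG2.

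After HSF1 siRNA 0 genes passed limma under the filters, normalizations and trend, and 9 passed in the fit of 4 arrays, which called 4 lists. The difference between hepatocytes and HepG2 gave 82 genes without the pairing and 249 without the HSF1 siRNA pair, and the causes were not tested. A mean-variance trend also ended the calls of KRT23 (adjusted p = 0.0596) and DAO (adjusted p = 0.128) there. The slope between siRNA pairs was 0.941 for genes chosen at 0.58 log2 units and 0.961 after quantile normalization, against 0.954, and the cause was not tested. The correlation of the viruses in HepG2 was 0.339 with the control siRNA pair, where no array is shared, and 0.375 without a filter. In C2C12 529 genes differed by at least 1 log2 unit without a filter and 511 after median centring. Among named genes, alternatives left 1869 results alike in hepatocytes, 201 gained and 93 lost a call. In HepG2 1188 were alike, 5 gained and 51 lost it, after HSF1 siRNA 808 were alike and 4 gained it, and between the cells 64 were alike and 6 lost it. Signal over background limits dim genes, whose differences RMA compresses, and the simulated changes of 0.5 log2 units recovered 0% of genes in each fit.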

Other observations

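The genes that moved alike in all cells were chosen only after the result was seen, and no test was run on them. Among 9628 genes measured in hepatocytes, HepG2 and C2C12, 33 were called and higher by at least 1 log2 unit in both human cells and higher by at least 1 in C2C12, 14 were lower in the same way, and 0 were opposite in C2C12. STARD5, a carrier of sterols, stood at 2.00 in hepatocytes, 2.53 in HepG2 and 2.35 in C2C12, PPTC7, a mitochondrial phosphatase, at 1.46, 1.85 and 1.83, and FASTKD1, which acts on mitochondrial RNA, at 2.04, 2.63 and 1.54. MTX3 and MTX1, parts of the outer mitochondrial membrane sorting machinery, stood at 1.71, 1.55 and 1.48 and at 1.00, 1.21 and 1.36. COQ5, of coenzyme Q synthesis, stood at 1.35, 1.35 and 1.38, SIRT5, a mitochondrial deacylase, at 1.28, 1.02 and 1.52, and TACO1, a translational activator of cytochrome oxidase, at 1.84, 1.77 and 1.20. DHRS11 stood at 2.40, 1.20 and 2.17 and ATG4D, an autophagy protease, at 1.52, 2.00 and 1.03.

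Among the genes lower in all cells ARID5B stood at -2.28 in hepatocytes, -3.00 in HepG2 and -1.51 in C2C12, TRIB1 at -2.65, -2.13 and -1.17, KLF6, a zinc finger factor, at -1.91, -1.99 and -1.05, PLK2, a polo-like kinase, at -1.95, -1.88 and -1.02, and OTUD1, a deubiquitinase, at -1.62, -2.10 and -1.26. CCN2, a target of YAP and of TGF beta signalling, stood at -1.03, -1.43 and -1.11, and AHR at -1.08, -1.73 and -1.10. With 1 array per virus in C2C12, these values have no replicate check there.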
